A study of Nonomuraea gerenzanensis with 12 samples.

How the data were processed

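The study measured RNA of Nonomuraea gerenzanensis mycelia, wild type and wblA knockout, collected at 48 h and 72 h of fermentation from 3 independent biological replicates each, per the labels. Per the labels' protocols, total RNA was prepared with a kit for bacterial RNA and sequenced on an Illumina NovaSeq instrument as 150 bp paired-end reads, and HTSeq 0.6.1 counted the reads mapped to each gene. The aligner, the genome build, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense loci may be shared between them, and reads of near-identical loci may have been split or dropped.

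The deposited table gives, for each of 11557 loci, a raw count per library, an FPKM value per library and a size in bases. Per the file headers and the values, the counts are whole numbers without normalization, and the deposited FPKM values were made by the authors from those counts, the size of the locus and the library's sum over the listed loci. All sizes are multiples of 3, so they are coding lengths. No locus has a gene or product name in the table, and no genome or annotation was used here. Lists of product names had been fixed for pathways and families, along with the wblA target and the A40926 cluster, and with no names they were not analysed here. No column of values was left unused.

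The design had been fixed before the data were examined for a table of FPKM alone, with limma on log2(FPKM + 1). As the table holds counts, the test that fits counts was used in its place: edgeR 4.0.16 in R 4.3.3, with TMM scaling, a model of the 4 group means over all 12 libraries, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the tested loci and a threshold of 0.05. The limma fit is kept among the alternatives, with limma 3.58.1. Loci with an FPKM of at least 1 in at least 3 libraries were tested, 10581 in all, and 976 were left out, which hold at most 0.0523% of the counts of any library. RPM and CPM are relative to the library's sum over the listed loci, and scaled CPM is divided by the TMM factor. Standard errors are the size of the log2 fold change over the square root of the F statistic. The contrasts were knockout against wild type at each time and averaged over both, 72 h against 48 h in each strain, and the difference of the knockout effects between the times.

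On simulated counts for the 10581 loci, drawn from the real means, dispersions and library sizes, the step recovered 13 of 100 loci changed 2-fold and 80 of 100 changed 4-fold for the knockout at 48 h. For the knockout at 72 h it recovered 10 and 73 of 100, for the average of both times 46 and 96, for time in wild type 14 and 82, for time in the knockout 10 and 75, and for the difference of effects 0 and 36. False calls made up at most 4.60% of the calls in these simulations, in that for the knockout at 72 h. Each simulation changed only 100 loci by 2-fold and 100 by 4-fold, and at most 148 passed. In the data 3083 passed for the knockout at 72 h, so the adjusted threshold was stricter in the simulations. The changed loci were also drawn only from loci above a floor on the mean scaled CPM, so recovery was not simulated for the loci with the fewest reads. The recoveries are therefore not the shares of real changes that were found.

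Library totals ranged from 4869431 to 10401397 counts, the TMM factors from 0.743 in a knockout library of 72 h to 1.49 in a wild-type library of 48 h. A count of 0 over a group was set against a floor of 3 reads over that group, and a fold against such a group is given as a lower bound. That bound takes the count of the other group as exact, and it uses library totals without TMM factors. The exact 95% interval of the same ratio starts lower, as at 165 in place of 203 for N_sp-plasmid2_orf0012 at 48 h. Ratios of reads also use library totals, and have exact 95% intervals conditional on their sum. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Replicate pairs were compared by a chi-square statistic over loci, which was between 10.0 and 171 per degree of freedom.

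With no names in the table, the loci named in the text follow the rule fixed for that case: at most 2 that rose and 2 that fell per comparison. They are those with the largest log2 fold change among loci past the threshold whose 3 values in a group all lie beyond all 3 in the other. For the difference of effects, those groups were the strains at the time with the larger knockout effect on the locus. The grouping by replicon, the runs and the blocks of numbers were chosen after the data were examined. A run is a stretch of at least 5 consecutively numbered loci that all passed in the same direction, and the shares of up to 3 of the longest per direction were computed. A block is 100 consecutive numbers of the chromosome. Runs were set against 1000 shuffles of the results over the loci. Such shuffles remove any likeness of neighbouring loci, so they show that results cluster in the numbering and not why. For the knockout at 48 h, log2 fold changes of consecutively numbered chromosomal loci had a Pearson correlation of 0.640. At 50 tested loci apart it was 0.149. Replicons were tested as sets with camera at a preset correlation of 0.01 and with an estimated correlation. For plasmid2, camera's adjusted p was 1.3e-20 at 48 h and 1.6e-09 at 72 h, and with an estimated correlation the adjusted p was 0.000202 at 48 h and 0.000611 at 72 h. For plasmid1 it was 0.646 and 0.937, and 0.959 at both times with an estimated correlation. Figures were drawn with matplotlib 3.10.9.

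The alternatives were other pseudocounts, filters and scalings, fits with a replicate block, fits to only the libraries compared, robust and weighted fits, and each replicate left out in turn. Others were added after the data were examined, among them DESeq2 1.42.0, library totals without TMM, thinned libraries, a depth class as a covariate, fits without the most abundant locus or the plasmids, and a fit without the 2 libraries that stand farthest from their groups.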

Results

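RNA was sequenced from mycelia of the actinomycete Nonomuraea gerenzanensis, the filamentous soil bacterium that makes the glycopeptide antibiotic A40926, of which B0 is the main component and from which the drug dalbavancin is made. The wild type was compared with a strain in which wblA was knocked out. WblA belongs to the WhiB-like family, iron-sulfur proteins of actinomycetes that act in the control of transcription and development. Mycelia were taken at 48 h and at 72 h of fermentation, and each of the 4 combinations of strain and time had 3 independent biological replicates, 12 libraries in all. The deposited table lists 11557 loci, of which 11490 are named for the genome, 55 for plasmid1 and 12 for plasmid2. Library totals ran from 4869431 to 10401397 counts, and the lowest and highest totals by group were 5037380 and 9783974 in wild type at 48 h, 4869431 and 9581762 in the knockout at 48 h, 5184427 and 8613105 in wild type at 72 h, and 8481484 and 10401397 in the knockout at 72 h. A single chromosomal locus took between 11.5% and 19.5% of the counts of each library. The files give identifiers without gene names, so the transcript of wblA itself and the A40926 cluster were not analysed here by name, and loci are described by identifier, by replicon and by runs of consecutively numbered loci. Whether neighbouring numbers are neighbours on the chromosome is not stated in the files. Values after a ± sign are standard deviations over 3 libraries unless a standard error (SE) is named.

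The libraries separated by time and by strain. The principal component with the largest share held 47.7% of the variance of log2 CPM and parted 48 h from 72 h, with the knockout farther out than the wild type at both times. The next component held 21.9% and parted the strains. Pearson correlations across loci lay between 0.946 and 0.980 within groups and between 0.812 and 0.952 between groups; loci are not independent replicates, so these values describe the libraries only. No pair of replicates agreed within sampling noise.

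**Figure D1:**
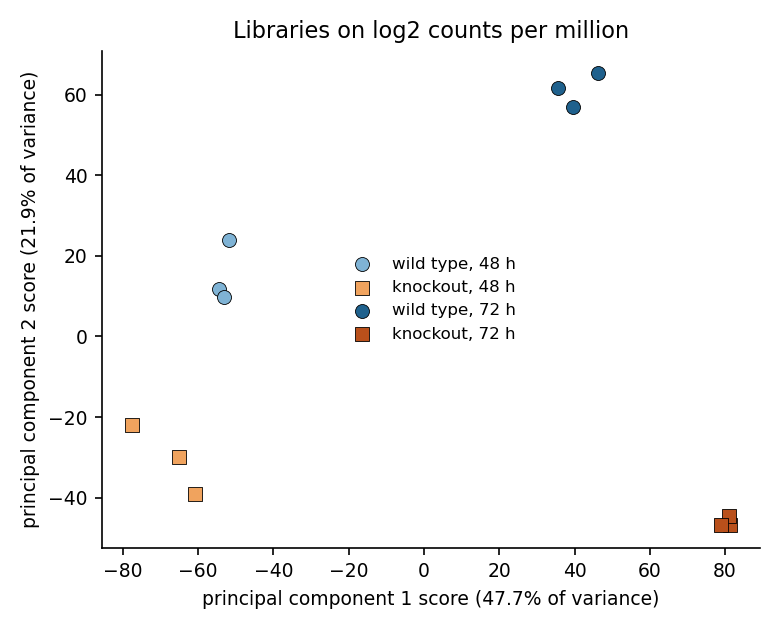
Scores of the 12 libraries on the leading principal components of log2 CPM, with 1 point per library, circles for wild type and squares for the wblA knockout, light for 48 h and dark for 72 h. The horizontal axis holds 47.7% of the variance and parts the times, and the vertical axis holds 21.9% and parts the strains.

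The comparison of the strains at 48 h asks which transcripts differ between the wblA knockout and the wild type early in the fermentation. Transcripts of plasmid2 were nearly absent from the knockout: the 3 wild-type libraries held 1596 reads on its 12 loci, or 67.4 ± 16.3 RPM, and the 3 knockout libraries held 2, a ratio of 669 in RPM (95% exact interval 185 to 5528, counting error only). Of the 11 plasmid2 loci tested, 6 fell, and 10 fell when adjusted over the list alone. Both named loci that fell lie there: N_sp-plasmid2_orf0012 had 726 wild-type and 0 knockout reads and was at least 203-fold lower (adjusted p = 0.000153), and N_sp-plasmid2_orf0007 had 204 and 0 reads and was at least 57.0-fold lower (adjusted p = 0.000679), both set against a floor of 3 reads over the group. On the chromosome 490 loci rose, and 203 of them lay in 5 blocks of 100 consecutive numbers, in which 135 rose without wild-type replicate 1 of 48 h. In the block that holds N_sp-genome_orf3497, 82 of 96 tested loci rose, and the block's share of the library went from 0.155% ± 0.0907 in wild type, or 0.103% without replicate 3, to 1.17% ± 0.0628 in the knockout.

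N_sp-genome_orf3497 itself had 0 reads in the wild type and 48 in the knockout at 48 h, at least 19.1-fold higher (adjusted p = 0.00203). N_sp-genome_orf8880 had 2.21 ± 0.909 scaled CPM in wild type and 274 ± 290 in the knockout, a log2 fold change of 6.91 (SE 1.07, adjusted p = 0.00137). Its knockout libraries held between 53 and 3279 reads, and the mean without replicate 2 was 119 scaled CPM. That rise had an adjusted p of 0.138 in limma-voom with library weights and passed in the other 33 of 34 alternatives, where the lowest adjusted p was 4.44e-10. The longest runs in which every consecutive locus rose had 22, 18 and 16 loci. The run of 22 went from 0.0281% ± 0.00942 of the counts in wild type to 0.368% ± 0.281 in the knockout, or 0.207% without knockout replicate 3. The run of 18 went from 0.0187% ± 0.0129, or 0.012% without wild-type replicate 3, to 0.233% ± 0.0104, and the run of 16 from 0.0079% ± 0.00488 to 0.0828% ± 0.0286.

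By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 685 of 10581 tested loci differed between the strains at 48 h, 490 higher and 195 lower in the knockout, and 627 of them differed by at least 2-fold. Runs of 5 or more such loci held 208 of the 685, against a highest value of 0 in 1000 shuffles of the loci, and they held 105, 97 and 131 without wild-type replicates 1 and 2 or knockout replicate 2 of 48 h. Runs of 3 or more held 330. With only the 6 libraries of 48 h in the fit 403 loci were called and runs held 98, without wild-type replicate 2 of 48 h 444 were called, and with a mean FPKM of at least 10 runs held 115. In limma-trend on FPKM rescaled to the same sum in each library, 430 of 701 loci were higher, and with library totals in place of TMM the median log2 fold change of all tested loci moved from -0.02 to -0.18.

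**Figure D2:**
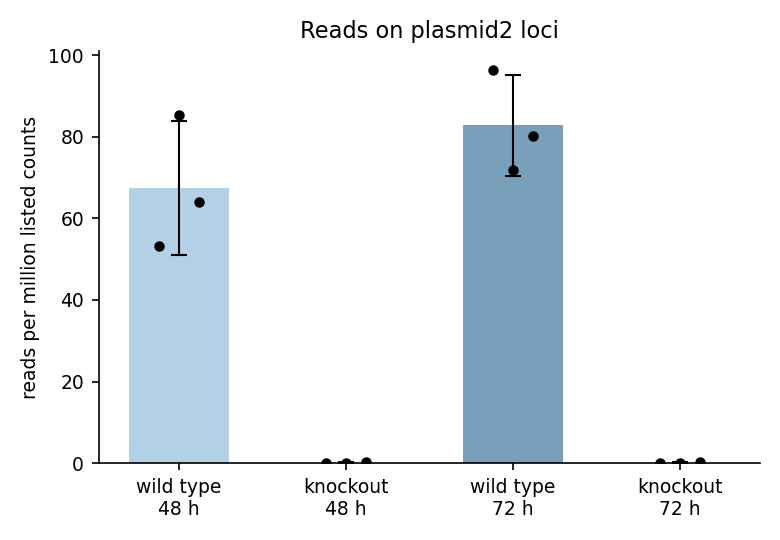
Reads on the 12 plasmid2 loci as RPM of the listed counts of the library, with 1 point per library, bars at the mean of 3 libraries and error bars of 1 standard deviation. The wild-type libraries sit between 53.1 and 96.2 RPM, and the highest knockout library is at 0.205.

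At 72 h the same comparison asks which transcripts differ between the strains later in the fermentation. Transcripts of plasmid2 were again nearly absent from the knockout, with 1801 wild-type reads, or 82.8 ± 12.4 RPM, against 2 knockout reads, a ratio of 1159 (95% exact interval 320 to 9577). Of its 11 tested loci 9 fell, and 10 fell when adjusted over the list alone. N_sp-plasmid2_orf0009 had 862 and 0 reads and was at least 370-fold lower (adjusted p = 2.42e-06), and N_sp-plasmid2_orf0012 had 573 and 0 reads and was at least 246-fold lower (adjusted p = 1.52e-05). Both chromosomal loci named for their rise lay in runs of consecutively numbered loci that rose together. A run of 11 loci that holds N_sp-genome_orf2068 took 0.00569% ± 0.000754 of the counts in wild type and 1.496% ± 0.179 in the knockout, where all 11 loci rose.

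N_sp-genome_orf2068 went from 6.61 ± 1.44 scaled CPM in wild type to 5614 ± 784 in the knockout at 72 h, a log2 fold change of 9.71 (SE 0.50, adjusted p = 4.97e-08). N_sp-genome_orf5831 had 0 reads in wild type and 1614 in the knockout, at least 418-fold higher (adjusted p = 9.14e-07). It lies in another run of 11 loci, all of which rose, from 0.00269% ± 4.67e-05 of the counts to 0.0489% ± 0.00801. The longest run that rose had 23 loci and went from 0.790% ± 0.286 to 6.89% ± 3.47. Among the runs that fell, 26 consecutive loci went from 0.449% ± 0.0608 in wild type to 0.0934% ± 0.0313 in the knockout, 16 loci from 0.0553% ± 0.00226 to 0.0112% ± 0.00109, and 15 loci from 0.225% ± 0.0015 to 0.0506% ± 0.0127. Of the 48 tested plasmid1 loci, 1 rose and 5 fell. With 1 library left out between 0 and 2 rose and between 4 and 6 fell, while with library totals in place of TMM 1 rose and 9 fell. On the chromosome 14.5% of tested loci rose and 14.6% fell. Reads on all plasmid1 loci together were at 3974 ± 2174 RPM in wild type and 11225 ± 8071 in the knockout at 72 h. The knockout libraries of 72 h ran from 5468 to 20451 RPM, and the highest wild-type library was at 5643. At 48 h the levels were 3200 ± 552 and 6639 ± 2974 RPM.

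The edgeR test called 3083 loci at 72 h, 1529 higher and 1554 lower in the knockout, of which 2182 differed by at least 2-fold. Runs of 5 or more held 689 of them, against at most 33 in 1000 shuffles, and they held 372, 394 and 427 without wild-type replicates 1, 2 and 3 and 422 and 385 without knockout replicates 1 and 2 of 72 h. Runs of 8 or more held 213 and runs of 3 or more 1382. The balance of directions depends on the scaling: with library totals in place of TMM factors, 886 were higher and 2120 lower, and the median log2 fold change of all tested loci moved from -0.04 to -0.29. With limma-voom and library weights the count was 5035, of which runs held 1548.

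**Figure D3:**
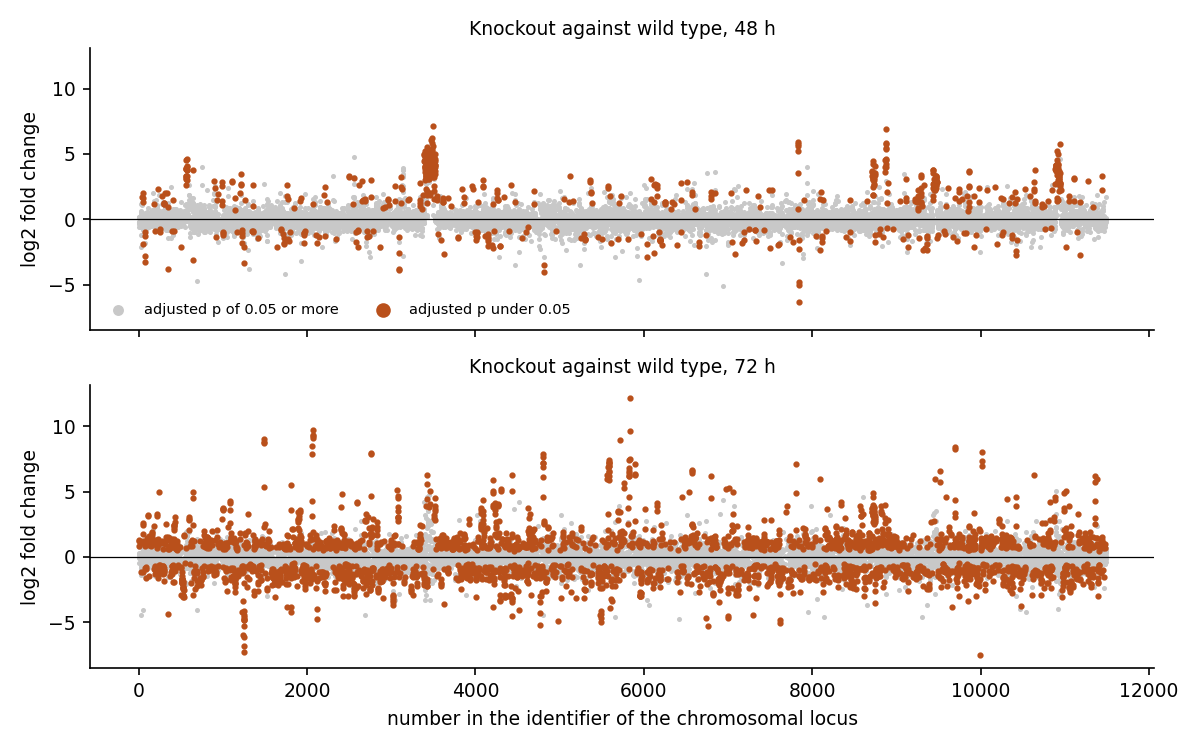
Log2 fold change of the knockout against the wild type for each tested chromosomal locus, by the number in its identifier, at 48 h above and at 72 h below, with 1 point per locus and coloured points for an adjusted p under 0.05. At 48 h 203 of the 490 rises lie in 5 blocks of 100 numbers, and at 72 h the 3068 coloured points lie in both directions, with 41 rises in the block that holds most.

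Whether the effect of the knockout was shared between the times was asked from separate libraries. At both times 87 loci rose, against 70.8 for independent lists, and 133 fell, against 28.6, while 27 went in opposite directions, against 100. With 1 library left out these counts ran from 45 to 127, from 85 to 185 and from 10 to 54. Of the 11 plasmid2 loci, 10 fell in the average of both times. Averaged over 48 h and 72 h, edgeR called 2498 loci, 1352 higher and 1146 lower in the knockout, and 1159 of them differed by at least 2-fold. With library totals in place of TMM the split was 789 higher and 1798 lower, and the median of all tested loci was -0.22. Across loci the log2 fold changes of the times had a Pearson correlation of 0.244 and a Spearman correlation of 0.182. The 220 loci shared in direction became 118 when each time was fitted alone, and 138, 133 and 145 without wild-type replicate 2, knockout replicate 1 or knockout replicate 2 of 48 h.

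The effect of time in the wild type asks which transcripts change between 48 h and 72 h with wblA in place. The longest run that rose held 47 consecutive loci with 71.7 kb of coding length, and its share of the counts went from 5.23% ± 1.42 at 48 h to 18.5% ± 1.23 at 72 h. A run of 33 loci rose from 0.0575% ± 0.0409, or 0.0339% without replicate 3 of 48 h, to 1.16% ± 0.394, and a run of 22 loci from 0.614% ± 0.287 to 2.72% ± 0.293. In the other direction, 20 consecutive loci fell from 5.60% ± 1.61 of the counts to 0.0871% ± 0.00913. N_sp-genome_orf4428 had 0 reads at 48 h and 122 at 72 h, at least 43.1-fold higher (adjusted p = 0.000306), and N_sp-genome_orf4772 had 1 and 159 reads, a ratio of 169 (95% exact interval 29.8 to 6704, adjusted p = 0.00117). N_sp-genome_orf10895 fell from 143 reads to 0, at least 44.9-fold lower (adjusted p = 0.00357). N_sp-genome_orf3419 fell from 456 reads to 1, a ratio of 430 (95% exact interval 76.8 to 17014, adjusted p = 0.00210), and missed the threshold in 2 of 34 alternatives, over which the adjusted p ranged from 4.36e-06 to 0.0632. Single wild-type libraries carried much of these levels: without replicate 3 of 72 h N_sp-genome_orf4428 went from 5.29 to 2.91 scaled CPM, without replicate 1 of 72 h N_sp-genome_orf4772 from 9.22 to 4.09, and without replicate 3 of 48 h N_sp-genome_orf3419 from 21.1 to 6.28.

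With edgeR 3438 loci changed with time in the wild type, 1731 higher and 1707 lower at 72 h, and 2566 changed by at least 2-fold. Runs of 5 or more held 759 of them, against at most 41 in shuffles, while runs of 8 or more held 353 and runs of 3 or more held 1455. With library totals in place of TMM, 1022 of 3941 called loci were higher and 2919 lower, and the median of all tested loci moved from -0.04 to -0.45. Log2 fold changes and calls with time are therefore relative to the TMM scaling. Shares of the counts, ratios of reads and lower bounds rest on library totals instead. TMM factors were lower at 72 h than at 48 h in both strains, so falls come out larger and rises smaller on library totals. For N_sp-genome_orf3419 the fitted fold with TMM was 326, against 430 in reads.

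In the knockout, the change between 48 h and 72 h included many of the same loci. Both strains raised 775 loci, against 329 for independent lists, and lowered 1011, against 344, and 108 went in opposite directions, against 673. With 1 library left out between 50 and 154 went in opposite directions. The longest run that rose held 36 loci and went from 0.378% ± 0.197 of the counts at 48 h to 9.14% ± 4.31 at 72 h. It overlaps the wild-type run of 33, all of which rose in the knockout too. Runs of 44 and 35 loci fell, from 1.18% ± 0.142 to 0.0148% ± 0.00322 and from 0.416% ± 0.316, or 0.234% without replicate 3 of 48 h, to 0.00256% ± 0.000119. Of the wild-type run of 47, 23 loci rose in the knockout with TMM scaling, while with library totals 12 rose and 5 fell, and its share was 6.59% ± 1.88 at 48 h and 8.33% ± 2.72 at 72 h. The run was chosen because all its loci passed in wild type, so that choice favours fewer passing in the knockout.

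N_sp-genome_orf1488 rose from 1.71 ± 0.413 to 2508 ± 425 scaled CPM in the knockout, a log2 fold change of 10.47 (SE 0.39, adjusted p = 5.36e-09), and N_sp-genome_orf1485 from 1.98 ± 0.259 to 2377 ± 1652, or 1424 without replicate 3 of 72 h, a log2 fold change of 10.21 (SE 0.56, adjusted p = 8.99e-08). N_sp-genome_orf10887 fell from 2422 reads to 3, a ratio of 1169 (95% exact interval 399 to 5670, adjusted p = 2.06e-06), and N_sp-genome_orf10916 from 240 reads to 0, at least 116-fold lower (adjusted p = 3.73e-05); both lie in the run of 35 loci that fell. Without replicate 3 of 48 h the level of N_sp-genome_orf10887 at 48 h was 69.0 in place of 131 scaled CPM. Its fitted fold with TMM was 882, below the 1169 in reads, and the bound for N_sp-genome_orf10916 rests on library totals too. The edgeR test called 4141 loci, 2011 higher and 2130 lower at 72 h, with 3151 changed by at least 2-fold. With library totals in place of TMM, 981 of 4467 were higher and 3486 lower, and the median of all tested loci was -0.53.

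**Figure D4:**
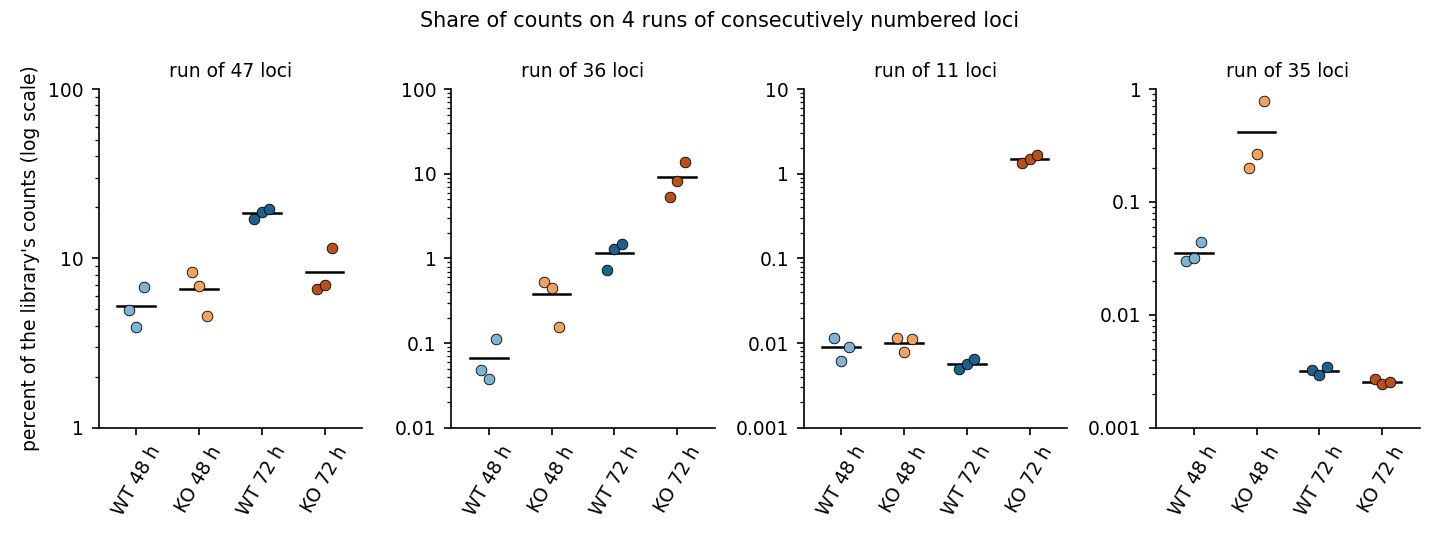
Percent of each library's counts on 4 runs of consecutively numbered loci, on log axes, with 1 point per library and a line at the mean of 3 libraries. From left to right are the run of 47 that rose with time in wild type (18.5% at 72 h), the run of 36 that rose with time in the knockout (9.14% at 72 h), the run of 11 with N_sp-genome_orf2068 (1.496% in the knockout at 72 h) and the run of 35 that fell with time in the knockout (0.416% at 48 h, 0.234% without replicate 3).

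The difference between the knockout effects at 72 h and at 48 h equals the difference between the time effects of the strains. It tests for which transcripts the signed knockout effect differs between the times, so loci whose effect reverses its direction can pass too. A run of 11 loci that holds N_sp-genome_orf5831 passed as a whole in the upward direction, as did 10 loci of the other run of 11 that rose in the knockout at 72 h. In the downward direction, 25 consecutive loci passed, whose share was 0.499% ± 0.099 in wild type and 0.527% ± 0.101 in the knockout at 48 h, and 0.446% ± 0.0605 and 0.0926% ± 0.0313 at 72 h. Another 20 consecutive loci passed downward, with shares of 0.611% ± 0.287 and 1.45% ± 0.272 at 48 h and of 2.71% ± 0.293 and 1.09% ± 0.323 at 72 h. Their median log2 fold change of the knockout against the wild type was 1.37 at 48 h and -1.02 at 72 h. Of the 47 loci that rose together in the wild type, 14 passed downward with TMM scaling and 26 with library totals. With 1 library left out that number ran from 7, as without wild-type replicate 1 of 72 h, to 29, as without wild-type replicate 3 of 48 h, and 11 of the 12 libraries moved it in this way. The run of 47 was chosen by its rise in wild-type libraries that the interaction test also uses, so that choice favours downward differences. In the same way, choosing the runs of 11 by their rise in the knockout at 72 h favours upward differences.

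Among the loci that met the naming rule, N_sp-genome_orf5831 had the largest upward difference, 11.92 on the log2 scale (SE 1.08, adjusted p = 7.84e-05). It had 0 wild-type reads at 72 h, so the size of that value depends on the prior count. N_sp-genome_orf6938 had an adjusted p of 0.0183 on few reads, 15 in wild type and 0 in the knockout at 48 h, and 0 and 7 at 72 h, and 0.0615 with the libraries thinned to the smallest total, the highest of 30 alternatives, of which the lowest was 5.59e-05 and 29 passed. N_sp-genome_orf3403 had 6 and 152 reads at 48 h and 3 and 0 at 72 h (adjusted p = 0.0493), and passed in 17 of 32 alternatives, over which the adjusted p ranged from 0.000535 to 0.231. N_sp-genome_orf3497, with 3 and 2 reads at 72 h, had an adjusted p of 0.0236, which ranged from 0.00066 to 0.130 over its alternatives. The edgeR test called 1566 loci, 751 upward and 815 downward. With library totals the split was 427 and 877 around a median of -0.11, with library weights in limma-voom the count was 2824, and without single libraries it was as low as 945.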

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

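The tests on plasmid2, the breakdown of the regroupings by the labels of 72 h, and those of depth and of single libraries for the smaller number of loci at 48 h, were chosen after the results were seen; the others were set beforehand. The interaction test found that the effect of the knockout differed between 72 h and 48 h for 1566 loci. Among the loci named in the comparisons, the log2 difference of the knockout effect, 72 h less 48 h, was 11.92 for N_sp-genome_orf5831, 9.49 for N_sp-genome_orf6938, 8.93 for N_sp-genome_orf1485, 8.80 for N_sp-genome_orf1488 and 8.76 for N_sp-genome_orf2068. It was -8.13 for N_sp-genome_orf3403, -7.93 for N_sp-genome_orf10916, -7.77 for N_sp-genome_orf3497, -7.14 for N_sp-genome_orf8880 and -4.86 for N_sp-genome_orf10887. Where a group had 3 reads or fewer, as for N_sp-genome_orf5831 in wild type at 72 h, the fitted value depends on the prior count and bounds nothing.

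When the strain labels were regrouped within each time, 4 of 100 regroupings drawn from 200 possible, the real one included, gave as many interaction loci as the real 1566, with a highest other count of 2211. The 3 others were among the 12 drawn, the real one included, that kept the 6 libraries of 72 h together by strain, and the highest count with the 72 h strains mixed was 19. The regroupings therefore follow the strain difference at 72 h and do not decide whether chance is excluded for a difference of effects. For the average of both times 1 of 100 regroupings reached the real 2498, with a highest other count of 2037. That share is under 0.05, which argues against chance alone for a strain difference in at least 1 of the times but does not exclude it. The highest count with the 72 h strains mixed was 11, so these counts also follow 72 h and do not decide on 48 h. For the 220 loci shared in direction 1 of 100 regroupings reached that number, with a highest other count of 5. Regrouping a time left at most 10 loci at 48 h and 0 at 72 h, so almost none could be shared. Whether the sharing exceeds chance is not decided by that test. For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many loci, and the real count and the highest other were 685 and 10 for the knockout at 48 h, 3083 and 0 at 72 h, 3438 and 0 for time in wild type, and 4141 and 0 for time in the knockout.

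Plasmid2 reads were nearly absent from the knockout at both times. At the mean wild-type share, 3646 plasmid2 reads would be expected in the 6 knockout libraries and 4 were counted, which argues against a lower depth of those libraries. The number of libraries with a plasmid2 share on the other strain's side was 0, but an exchange of all libraries between the strains would give the same 0, so that stays open. Loss of plasmid2 from the knockout strain is a candidate explanation, as a hypothesis: 0 of the 12 loci had more than 3 reads over the 6 knockout libraries. Silencing of plasmid2 without its loss cannot be told apart from loss with RNA alone, since 4 reads over the 6 knockout libraries fit either.

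Fewer loci passed between the strains at 48 h than at 72 h. Over 5467 loci with a mean of at least 10 RPM, the noise-subtracted standard deviation of the strain difference was 0.74 at 48 h and 1.28 at 72 h on the log2 scale, a ratio of 1.73, and the lowest ratio with 1 library left out was 1.49, which argues against a larger replicate spread at 48 h as the whole cause. With every library thinned to the smallest total, 642 and 2827 loci passed, a ratio of 4.40, which argues against depth. The highest count at 48 h with 1 library of 48 h left out was 759, so no single library of 48 h held the count down to this extent. A strain difference that grows with time may then account for this, as a hypothesis found on the same data, and no test separated wblA from a possible loss of plasmid2.

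The change between 48 h and 72 h was larger in the knockout than in wild type. The noise-subtracted standard deviation was 1.68 in the knockout and 1.27 in wild type on the log2 scale, a ratio of 1.32, with a two-sided exact permutation p of 0.01 over 200 regroupings, which can give no p under 0.005. The highest ratio of another regrouping was 1.33, and of the 20 regroupings that kept the 72 h libraries together by strain 2, the real one included, gave as large a ratio, so the p follows the strain difference at 72 h and leaves replicate spread open. The ratio was 1.33 with every library thinned to the smallest total and at least 1.28 with any 1 library left out, which argues against depth and a single library as the cause. A stronger response to time in the knockout strain stays open too and was not separated from a possible loss of plasmid2, and how far the cultures had grown at each time was not measured here.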

How the results depend on the processing

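DESeq2, library totals, thinning, the depth class, runs of 3 or 8 loci and the fits without the most abundant locus, the plasmids or 2 libraries were chosen after seeing the data. The limma fit planned beforehand, on log2(FPKM + 1), also gave mostly falls. For the knockout it had 856 loci higher and 2042 lower at 72 h, and 866 and 1799 on average. For time it had 1040 and 2723 in wild type and 983 and 3406 in the knockout, and for the difference of effects 452 and 1037. Time effects stayed within 1.5 times of their counts in all alternatives run, from 2566 to 4080 loci in wild type and from 3095 to 5144 in the knockout, and from 2480 to 3663 and from 3373 to 4404 with 1 library left out. With only the libraries compared, the knockout effect at 48 h had 403 loci and the overlap of both times 118, where fewer libraries set the spread. Of the calls with all libraries, 401 of 685 stayed at 48 h and 2955 of 3083 at 72 h. The replicate noise of the strain difference was 0.405 at 48 h and 0.318 at 72 h on the log2 scale. The 685 calls at 48 h therefore lean on a spread shared with the libraries of 72 h. Library weights in limma-voom gave 5035 loci for the knockout at 72 h and 2824 for the difference of effects, and the cause was not tested. A minimum change of 2-fold left 1159 of the average effect by its construction. With 1 library left out, the counts ran from 444 to 768 at 48 h, from 2251 to 3342 at 72 h, from 1985 to 2654 for the average, from 945 to 1870 for the difference of effects, and from 133 to 291 for the overlap. The 444 came without wild-type replicate 2 of 48 h. The difference of effects had 978, 1014 and 1037 loci without wild-type replicates 1, 2 and 3 of 72 h, 1034 without knockout replicate 2 of 48 h, and 1018 and 945 without knockout replicates 1 and 2 of 72 h. The share of variance on the leading component was 50.7%, 45.9% and 53.1% on log2 FPKM with pseudocounts of 1, 0.1 and 10, 54.0% with a mean FPKM of at least 10, and from 46.1% to 50.3% with 1 library left out. DESeq2 called 870, 3340, 2848, 3715, 4277 and 1985 loci for the knockout at 48 h, at 72 h and on average, for time in wild type and in the knockout, and for the difference of effects. In the same order thinned libraries gave 642, 2827, 2244, 3174, 3861 and 1322, and fits without the 2 libraries that stand apart 689, 3617, 2841, 3412, 4441 and 2251.

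The replicate block gave 629, 2856, 2310, 3169, 3897 and 1297 loci in that order and 202 for the overlap. The numbers did not pair the libraries over all groups: same-numbered libraries of different groups had correlations of their deviations from -0.326 to 0.497. Of these 4 of 18 were over 0.1, and 6 of 36 best matches had their own number. Between the strains at 48 h the correlations were 0.497, 0.219 and -0.0726 for replicates 1, 2 and 3. Differently numbered libraries reached 0.425, for wild-type replicate 1 of 48 h and knockout replicate 3 of 72 h. Over 20 results on named loci and 664 alternatives, 643 kept the direction and the side of the threshold, 21 missed the threshold and 0 reversed. Alternatives in which a locus had no adjusted p were not counted. Named loci were chosen for large changes with separated groups, so they do not speak for the other calls. Of all 685 loci called at 48 h, 401 stayed with only the libraries compared and 683 in the robust fit. Alternatives for the A40926 cluster bounds and the product-name lists were not run, as no locus has a name. Depth limits loci with few reads, such as N_sp-genome_orf6938, with 15 reads in the group where it had most.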

Other observations

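The windows and long loci were examined after the data were seen, and the test of missing chromosomal loci was set beforehand. The rises in the knockout at 48 h were concentrated in the numbering: the 5 blocks of 100 numbers with most of them held 203 of 490, or 41.4% (135 without wild-type replicate 1 of 48 h), and the block with most held 82, against at most 17 in 1000 shuffles of the results over the loci. The blocks that followed held 42, 34, 24 and 21. Loci of the block with 82 had a median coding length of 447 bases, against 828 over all tested loci. The share of that block was 0.0361% ± 0.00321 in wild type and 0.0228% ± 0.00632 in the knockout at 72 h, and 34 of its loci passed the interaction test downward, or 20 without wild-type replicate 1 or 3 of 72 h, 22 without knockout replicate 2 of 48 h and 21 without knockout replicate 2 of 72 h, and 73 with quantile normalization. The counts of 82 rises at 48 h and of 92 falls with time in the knockout were the same with median-ratio scaling, and with library totals they were 82 and 95. The block was chosen by its values in the knockout libraries of 48 h, which the time and interaction tests also use, so that choice favours falls in both.

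A run of 11 loci that rose with time in the knockout took 0.00226% ± 0.000429 of the counts in wild type and 0.00252% ± 0.000768 in the knockout at 48 h, and 0.00529% ± 0.000292 and 0.146% ± 0.0479 at 72 h. The run of 20 loci that fell with time in wild type went in the knockout from 3.49% ± 0.37 to 0.256% ± 0.0988, where 19 of them fell. Of 22 tested loci with a coding length of at least 5000 bases, 1 rose and 6 fell in the knockout at 72 h, and 10 fell without knockout replicate 3 of 72 h. The adjusted p of camera for that set was 0.0465 with the preset correlation and 0.342 with an estimated correlation. Over the chromosome 14.5% of tested loci rose and 14.6% fell at 72 h. Loci that passed were longer there too, with a median of 973.5 bases for falls, 870 for rises and 786 for the rest. Some of the 22 lie in the run of 47 that rose with time in wild type, so they are not separate observations.

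Whether a whole expressed chromosomal locus is missing from the knockout was tested by its reads. Of 10105 chromosomal loci with 30 or more wild-type reads, 0 had no read over the 6 knockout libraries. On plasmid2, which is nearly absent, 5 loci met this rule of exactly 0 knockout reads. The rule can still miss an absent locus, since N_sp-plasmid2_orf0009 had 2 knockout reads at 48 h against 479 in wild type. Whether a whole locus is missing therefore stays open, and a deletion of part of a locus was not tested.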
